A study of Mus musculus with 16 samples.

How the data were processed

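Total RNA of primary mouse lung fibroblasts, passaged at least 3 times and collected 48 hours after siRNA transfection, was labelled with Cy3 and hybridised per the labels to one-colour arrays with 62976 spots. The groups scr, siLox, siLoxl1 and siLoxl2 held 4 arrays each, and groups and replicate numbers were taken from the sample labels. Per the file headers, the scanner values are intensity values per spot, read with Agilent Feature Extraction 10.7.3.1, background subtracted and detrended within each array. The value table of the authors holds log2 values, quantile normalized between arrays: sorted columns differed by at most 0.000965, and the table correlated with the log2 scanner values at r = 0.997 to 0.999. Other columns used here are flags of 0 or 1 per spot, deposited with the scanner values.

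The scanner values were the basis of the analysis, and the value table served as an alternative. Spots marked as outliers were left out, the spots of a probe were averaged, and log2 values were taken relative to the 75th percentile of the non-control probes of each array. That percentile was 8.67 to 9.03 (log2) on slide 1 and 9.74 to 9.90 on slide 2, and 0 spots were saturated. Arrays of a group correlated at r = 0.988 to 0.994. Of 55681 non-control probes, 28026 (50.3%) had an accession in the RefSeq table of assembly GRCm38.p6, which was used for gene names only and changed the symbol of 1651 probes. Probe positions are those of the scanner files, in mouse build mm9. A probe was kept when it was well above background on all 4 arrays of at least 1 group (32478 probes, 58.3%), 48 of these were dropped because an array had no usable spot, and the brightest probe stood for a gene. This left 22644 genes, 6620 of them with over 1 detected probe.

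Genes were tested with limma 3.58.1 (lmFit, contrasts.fit, eBayes) in R 4.3.3, in 1 fit of all 16 arrays with a mean per group, and p-values were adjusted by Benjamini-Hochberg per comparison with a threshold of 0.05. The targeted genes were also tested with an exact two-sided permutation test. All 6 comparisons of the 4 groups were made. The slides were read from the headers of the scanner files. The slide cannot be a term in the 4 comparisons between slides, and within a slide it changes no estimate. The spread within groups was larger on slide 1 (median SD 0.163) than on slide 2 (0.0969), so that a fit of all 16 arrays is too lenient for siLox against scr and too strict for siLoxl1 against siLoxl2, and results of the 8 arrays of a slide alone are given beside it.

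The comparisons, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except that leaving out replicate 4 of both scr and siLox and the list calls from 8 arrays were added afterwards. A total of 25 lists were tested with camera (limma, preset correlation 0.01), adjusted over the lists of a comparison, with a correlation estimated from the data and with fry (limma) beside it. They are the lysyl oxidase family, fibrillar and associated collagens, collagen processing and cross-linking, the elastic fibre, other matrix glycoproteins and proteoglycans, matrix proteases and inhibitors, TGF-beta and BMP signalling, myofibroblast contractile genes, and lipofibroblast and alveolar fibroblast genes. Further lists are the interferon response, inflammatory cytokines and NF-kB targets, the cell cycle, p53 targets, the unfolded protein and amino acid response, hypoxia and glycolysis, cholesterol synthesis and uptake, serum response and immediate early genes, heat shock, ribosomal proteins and the RNA interference machinery. Markers of epithelial cells, endothelial cells, leukocytes and macrophages, mesothelial cells, and pericytes and smooth muscle complete them.

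The text names the 5 lysyl oxidase genes in every comparison. Per comparison with scr it names up to 8 genes with the highest and 8 with the lowest log2 fold change among those that passed, did not overlap between the groups and had a gene symbol that is not a clone or predicted name, and 5 on each side between siRNAs. Per list it names up to 4 members that passed with the largest fold, or 2 where none passed. Fn1, Saa3 between siLox and scr and, between siLoxl1 and siLoxl2, Il1rl1, Icam1, Plod1 and Plod2 were chosen after their values were seen. Where no array of a group was well above background, a fold is given as a lower bound for the brightest probe, which stands for the gene. Each array of that group then counts with the higher of its own value and the lowest value among the probes well above background on that array.

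The fit was tested on simulated data of 22644 genes with the spread of each slide and 200 changed genes. For siLox against scr, 62.7%, 85.1% and 98.5% of genes changed by 0.5, 1 and 2 (log2) were recovered, with 146 unchanged genes called (44.5% of the calls), and with the 8 arrays of slide 1 alone 40.3%, 71.6% and 90.9%, with 15 unchanged genes called (8.67%). For siLoxl1 against siLoxl2 the shares were 59.7%, 88.1% and 95.5%, with 9 unchanged genes called (4.81%), and with the 8 arrays of slide 2 alone 71.6%, 92.5% and 98.5%, with 17 unchanged genes called (8.37%). In the other 4 comparisons 15 to 18 unchanged genes were called. A list shifted by 0.5 was called in all 6 comparisons, and 0 other lists were called there by camera. The simulated genes were independent of each other, so false calls of lists of correlated genes could not appear there. The shares of false calls hold for 200 changed genes and do not carry over to the larger numbers called in the data. Alternatives were another background correction (normexp, offset 50), quantile normalization, the value table of the authors, no filter on dim probes, the mean of the detected probes of a gene, the 8 arrays of the groups compared, a replicate block, a slide block, eBayes with trend and robust, array weights (statmod 1.5.0), a fold threshold, leaving out each array, and scr arrays split into 2 and 2. Tables were read with the R package data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9.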

Results

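Gene expression was measured on 16 one-colour (Cy3) microarrays of primary mouse lung fibroblasts, taken 48 hours after a small interfering RNA (siRNA) had been brought into the cells. The cells had received a scrambled control siRNA (scr) or an siRNA against Lox (siLox), Loxl1 (siLoxl1) or Loxl2 (siLoxl2), with 4 arrays in each group. Lox, Loxl1 and Loxl2 encode lysyl oxidases, the enzymes that start the cross-linking of collagen and elastin. The series title speaks of exogenous expression, whereas every sample label describes a knockdown or its control, and the groups here follow the labels. Of 59305 non-control spots per array, 29205 to 30994 (49.2% to 52.3%) were well above background on slide 1 and 35839 to 37401 (60.4% to 63.1%) on slide 2. The number of arrays limits the precision of every value.

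The 8 scr and siLox arrays shared slide 1, and the 8 siLoxl1 and siLoxl2 arrays shared slide 2, with each group in a slide row of its own. The comparisons of siLox with scr and of siLoxl1 with siLoxl2 therefore lie within 1 slide, and each of the other 4 comparisons cannot be told apart from the difference between the slides. The first principal component held 70.7% of the variance and parted the slides. The second held 9.19% and parted siLox from scr, with scr replicate 4 and siLox replicate 4 nearest to each other. Whether the replicates were separate cultures is not given in the sources used here, so p-values measure only the spread between the samples. Fold changes below are log2 differences of group means with the standard error of the limma fit (± SE, n = 4 arrays per group), and levels are log2 signals relative to the 75th percentile of the array. Where a gene was above background on some arrays of a group only, their number is given, and its fold change there rests partly on signals at background and is not exact.

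**Figure D1:**
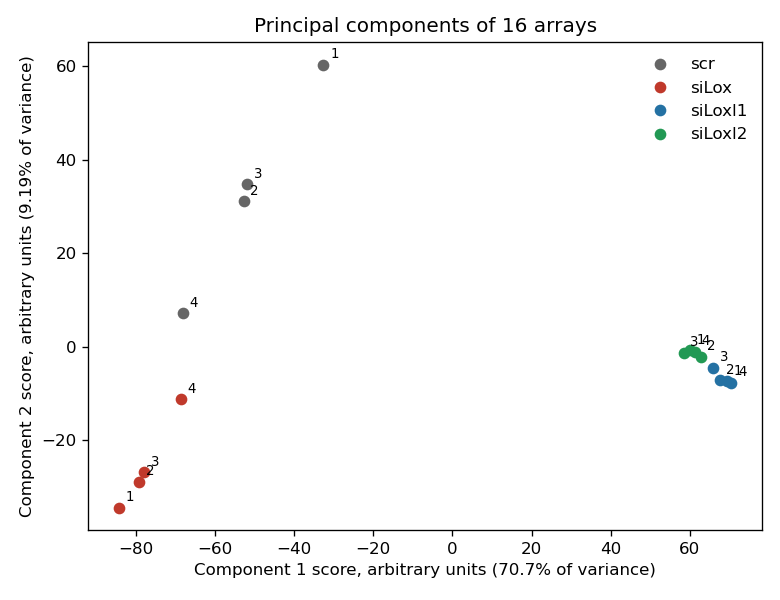
Scores of the 16 arrays on the first and second principal components of 22644 genes, in arbitrary units; each point is 1 array, coloured by group and labelled with its replicate number. The first component holds 70.7% of the variance and separates slide 1 (scr and siLox) from slide 2 (siLoxl1 and siLoxl2).

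The targeted genes were read first. Lox, read by a probe on chromosome 18 from 52676912 to 52676971 (mouse build mm9), had levels of 4.16, 4.08, 4.15 and 3.88 in scr replicates 1 to 4 and of 0.39, 0.89, 1.25 and 2.04 in siLox replicates 1 to 4. It stood at 4.53, 4.86, 4.68 and 4.93 in siLoxl1 and at 4.86, 4.96, 4.82 and 4.94 in siLoxl2. In siLox, 13.2% of the scr level remained (log2 fold change −2.92 ± 0.24, limma adjusted p = 2.71e-06). A second Lox probe gave −2.17. An exact two-sided permutation test of the 4 and 4 arrays gave p = 0.0286 at both probes, the smallest value that this design allows. Lox was higher than in scr in both groups on slide 2, by 0.68 ± 0.24 in siLoxl1 and by 0.83 ± 0.24 in siLoxl2.

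Loxl1 (chromosome 9, 58138570 to 58138629) had levels of 5.79, 5.60, 5.56 and 5.35 in scr and of 4.54, 4.54, 4.60 and 4.72 in siLoxl1. It read 5.65, 5.80, 5.79 and 5.78 in siLoxl2 and 4.89, 4.98, 5.10 and 5.38 in siLox. Loxl1 was lower in siLoxl1 than in scr (−0.98 ± 0.10) and, within slide 2, lower in siLoxl1 than in siLoxl2 (−1.15 ± 0.10, limma adjusted p = 4.15e-05), where 44.9% of the siLoxl2 level remained. An exact two-sided permutation test gave p = 0.0286 for both differences at both Loxl1 probes. Loxl2 (chromosome 14, 70095254 to 70095313) had levels of 6.80, 6.47, 6.42 and 6.09 in scr, 5.78, 5.51, 5.62 and 6.03 in siLox, 5.59, 5.81, 5.61 and 5.73 in siLoxl1, and 5.25, 5.58, 5.35 and 5.35 in siLoxl2. Loxl2 was lower in siLoxl2 than in scr (−1.06 ± 0.14, limma adjusted p = 1.04e-05), but it was also lower in siLoxl1 than in scr (−0.76 ± 0.14). Against scr the other 2 Loxl2 probes read −1.59 and −1.47 in siLoxl2 and −1.21 and −1.12 in siLoxl1. Within slide 2 the difference between siLoxl1 and siLoxl2 was 0.30 ± 0.14 and did not pass the threshold (limma adjusted p = 0.277; 0.0551 with the 8 arrays of slide 2 alone). The other 2 Loxl2 probes read 0.38 and 0.34 there. At each of the 3 probes the 4 siLoxl2 arrays lay below the 4 siLoxl1 arrays (exact two-sided permutation p = 0.0286, the smallest value that this design allows, not adjusted over the probes). By the exact test the groups did not overlap for Loxl2, as they did not for 20.3% of all genes in this comparison. The limma tests adjusted over all genes did not pass, so a lower Loxl2 in siLoxl2 within the slide is not established.

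**Figure D2:**
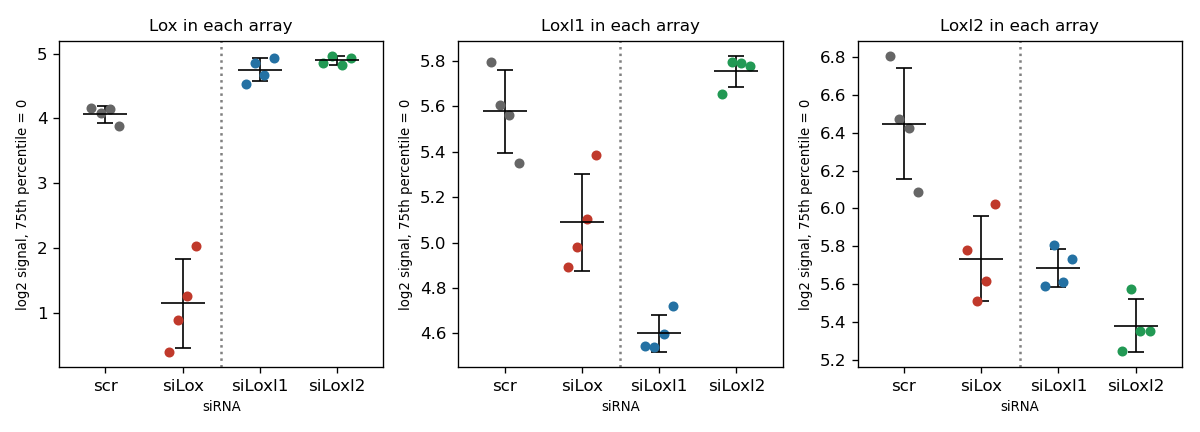
Levels of Lox, Loxl1 and Loxl2 (log2 signal relative to the 75th percentile of the array) in each of the 16 arrays; points are arrays, bars are group means with the standard deviation of 4 arrays, and the dotted line parts slide 1 from slide 2. Lox stands between 0.39 and 2.04 in siLox and above 3.8 in every other array, and Loxl1 is lowest in siLoxl1.

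The comparison of siLox with scr asks which transcripts change when Lox is knocked down, and it lies within slide 1. Genes of the elastic fibre and of collagens were lower in siLox, and genes of inflammatory signalling were higher. Of 19 genes of the elastic fibre, 15 fell and 0 rose (18 changed adjusted over the list alone). Adamtsl4, which acts on fibrillin microfibrils, fell by 1.32 ± 0.15, the microfibril gene Mfap2 by 1.19 ± 0.26, the elastin gene Eln by 0.95 ± 0.33 and Efemp1 by 0.81 ± 0.11. The list mean per array lay between −0.17 and 0.34 in scr and between −0.74 and −0.13 in siLox, with replicate 4 of both groups nearest to each other. The list was called lower by camera (adjusted p = 5.05e-05), and that call was lost with an estimated correlation (adjusted p = 0.562 with an estimated correlation). The fry test, which asks whether the genes of a list move one way and compares them with no others, gave an adjusted p of 0.00125. Its values for the other lists are not reported here. A split of these arrays that mixed the groups gave a larger median of the elastic fibre list (0.5364 against 0.4655 in size), so chance is not excluded for it. Of 17 fibrillar and associated collagens, 13 fell and 1 rose (14 adjusted over the list alone). Col6a3 fell by 1.06 ± 0.15, Col6a1 by 0.91 ± 0.17, Col5a2 by 0.80 ± 0.16 and Col6a2 by 0.69 ± 0.16. Of 23 genes of collagen processing and cross-linking, 16 fell and 1 rose (18 adjusted over the list alone), among them the lysyl hydroxylase genes Plod2 (−0.66 ± 0.17) and Plod1 (−0.64 ± 0.09) and the prolyl hydroxylase gene P4ha1 (−0.65 ± 0.15), while Pcolce2, an enhancer of procollagen processing, rose by 0.91 ± 0.15. Of 24 other matrix glycoproteins and proteoglycans, 16 fell and 2 rose (21 adjusted over the list alone), with the small proteoglycans Aspn at −2.35 ± 0.89 (above background on 2 of 4 siLox arrays), Lum at −1.20 ± 0.32, Fmod at −1.17 ± 0.18 and Ogn at −0.93 ± 0.25. These 3 lists were called lower with adjusted p = 0.00153 each, and each call was lost (adjusted p = 0.562 with an estimated correlation).

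Further lists were called lower in siLox, and the matrix proteases were not called. Of 30 genes of TGF-beta and BMP signalling, 14 fell and 6 rose (23 adjusted over the list alone), with Tgfbi at −0.88 ± 0.26, the repressor gene Ski at −0.84 ± 0.15 and Tgfb3 at −0.65 ± 0.13, whereas Bmp2 rose by 1.18 ± 0.24. Of 20 contractile genes of myofibroblasts, 9 fell and 1 rose (11 adjusted over the list alone), with Vcl at −0.49 ± 0.08 and Itga5 at −0.45 ± 0.08. Of 11 pericyte and smooth muscle markers, 7 fell and 0 rose (8 adjusted over the list alone), with Notch3 at −0.80 ± 0.14 and Pdgfrb at −0.79 ± 0.13. Of 24 genes of cholesterol synthesis and uptake, 13 fell and 0 rose (14 adjusted over the list alone). Dhcr7 fell by 0.88 ± 0.12 and Hmgcs1 by 0.85 ± 0.17. A second Hmgcs1 probe read 0.19. The calls of these 4 lists (adjusted p = 0.0240, 0.0182, 0.00259 and 0.00153) were lost as well (adjusted p = 0.562 with an estimated correlation). On replicate 4 the mean of the pericyte list was higher in siLox (0.27) than in scr (0.23). So were those of the contractile (−0.04 and −0.12) and cholesterol lists (−0.55 and −0.79), so that the groups overlapped in these lists. The same held for the collagens (0.35 and 0.18), other matrix genes (0.13 and 0.04) and collagen processing (−0.11 and −0.18). It also held for the elastic fibre (−0.13 and −0.17) and the matrix proteases (−0.36 and −0.49). The means of the TGF-beta list did not overlap (0.003 in siLox and 0.013 in scr on replicate 4). Of 22 matrix proteases and inhibitors, 11 fell and 4 rose (15 adjusted over the list alone), with Plat at −1.09 ± 0.24 and Adamts1 at −1.03 ± 0.17, and the list was not called (adjusted p = 0.0667). Ribosomal protein genes were called lower with a median of −0.09 (adjusted p = 0.0460), with 5 of 24 past the threshold (4 adjusted over the list alone). In the 8 arrays of slide 1 alone 0 of the 24 passed the limma test (4 at an unadjusted p under 0.05), and the list was still called (adjusted p = 0.0331). Quantile normalization turned that direction (median 0.03), and the adjusted p with an estimated correlation was 0.622.

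Among 27 inflammatory cytokines and NF-kB targets, 16 rose and 1 fell (18 adjusted over the list alone). The chemokine genes Cxcl2 and Cxcl1 rose by 2.15 ± 0.67 and 1.93 ± 0.44, and the colony-stimulating factor genes Csf3 and Csf2 by 2.09 ± 0.56 and 1.79 ± 0.55, with Csf3 above background on 3 of 4 scr arrays. These genes varied more between the scr arrays than between the siLox arrays (SD 1.73 and 0.35 for Cxcl2, 1.61 and 0.28 for Csf2). The list mean per array lay between −0.21 (replicate 1) and 0.95 in scr and between 1.13 and 1.44 in siLox. The list was called higher (adjusted p = 5.05e-05), and the call was lost with an estimated correlation (adjusted p = 0.562 with an estimated correlation). The mean of the leukocyte and macrophage markers lay between −0.73 and 0.17 in scr and between 0.03 and 0.29 in siLox, so that the groups overlapped, and the median difference of the list, 0.45, was 0.27 without scr replicate 1 and 0.71 without scr replicate 4. Of 17 such genes, 9 rose and 1 fell (12 adjusted over the list alone), with Itgax at 1.60 ± 0.44 (above background on 3 of 4 scr arrays), the scavenger receptor gene Marco at 1.08 ± 0.17, Laptm5 at 0.82 ± 0.29 and Tyrobp at 0.75 ± 0.22. That list was called higher too (adjusted p = 0.00758; adjusted p = 0.562 with an estimated correlation). Of 22 serum response and immediate early genes, 12 rose and 6 fell (18 adjusted over the list alone), with the transcription factor genes Egr1 at 1.15 ± 0.28, Junb at 1.08 ± 0.21 and Egr2 at 1.08 ± 0.22, and the list was not called (adjusted p = 0.0695). Of 42 interferon response genes, 11 rose and 4 fell (15 adjusted over the list alone), with Mx1 at 1.26 ± 0.42 and Mx2 at 1.11 ± 0.26, and that list was not called either (adjusted p = 0.0695). With the 8 arrays of slide 1 alone, 10 of them were higher and 3 lower, and the interferon list was called higher (adjusted p = 0.0249; adjusted p = 0.618 with an estimated correlation).

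The remaining lists were not called in siLox in the fit of 16 arrays. With the 8 arrays of slide 1 alone, the cell cycle and mesothelial lists were called lower (adjusted p = 0.0249 each; adjusted p = 0.618 each with an estimated correlation), with 12 of 41 and 5 of 9 genes lower and 1 higher in each. Of 29 genes of the unfolded protein and amino acid response, 17 fell and 5 rose (23 adjusted over the list alone), with Atf3 at 0.99 ± 0.20 and Vldlr at −0.89 ± 0.19. Of 41 cell cycle genes, 14 fell and 3 rose (17 adjusted over the list alone), with Ccne1 at −0.69 ± 0.07 and Ccnb2 at −0.56 ± 0.07. Of 13 genes of the RNA interference machinery, 5 fell and 0 rose (5 adjusted over the list alone), with the GW182 family members Tnrc6b at −0.77 ± 0.08 and Tnrc6a at −0.74 ± 0.09. Of 9 mesothelial markers, 6 fell and 1 rose (8 adjusted over the list alone), with Gpm6a at −0.68 ± 0.14 and Krt19 at 0.77 ± 0.10. Of 14 lipofibroblast and alveolar fibroblast genes, 7 fell and 2 rose (10 adjusted over the list alone), with Plin4 at −1.10 ± 0.21 (above background on 3 of 4 siLox arrays) and Fgf10 at −0.66 ± 0.06. Of 26 hypoxia and glycolysis genes, 11 fell and 4 rose (17 adjusted over the list alone), with Pdk1 at −0.65 ± 0.14 and Ndrg1 at 0.45 ± 0.09. Of 21 p53 targets, 6 fell and 5 rose (11 adjusted over the list alone), with Trp53inp1 at −0.94 ± 0.14 and Pmaip1 at 0.58 ± 0.10. Heat shock genes gave 3 lower and 1 higher of 13 (4 adjusted over the list alone), with Hsph1 at −0.39 ± 0.08. Epithelial markers gave 2 higher and 2 lower of 9 (4 adjusted over the list alone), with Hopx at −0.77 ± 0.10, and endothelial markers 2 lower and 1 higher of 10 (3 adjusted over the list alone), with Flt1 at −0.80 ± 0.11. Within the lysyl oxidase family, Loxl2 (−0.71 ± 0.14) and Loxl1 (−0.49 ± 0.10) fell with Lox, which left 3 of 5 changed (3 adjusted over the list alone), and Loxl3 (−0.04 ± 0.07) and Loxl4 (0.12 ± 0.09) did not pass the threshold. The Loxl4 probes disagreed: the second read −0.20 and passed (limma adjusted p = 0.0134 over all probes; exact two-sided permutation p = 0.0286), so that no direction is given for Loxl4.

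Single genes with the furthest changes are given here and below among those that passed, did not overlap between the groups and had a gene symbol that is not a clone or predicted name. In siLox they were, besides Cxcl2, Madcam1, an adhesion molecule gene (2.36 ± 0.48), the activation marker Cd83 (2.32 ± 0.58), Shisal1 (2.22 ± 0.59), the neurofilament gene Nefm (2.16 ± 0.28) and Prl2a1 (2.14 ± 0.54). Shisal1 and Nefm were above background on 3 of 4 scr arrays and Prl2a1 on 1. Pmfbp1 was at least 4.18-fold higher, with no scr array above background. Ear2 was above background on 1 siLox array and on 0 scr arrays, so no fold is given. After Lox itself, the synapsin gene Syn2 (−2.31 ± 0.37), S100b (−2.06 ± 0.28) and Rarres1 (−1.82 ± 0.22) fell furthest among those above background on at least 1 array of each group. Of the siLox arrays, Syn2 was above background on 2, S100b on 1 and Rarres1 on all 4. Aspn fell further than Syn2, with groups that overlapped. Lrrc4 was at least 2.46-fold lower, Alox5 at least 1.52-fold, Inpp5j at least 1.46-fold and Rgs7bp at least 1.27-fold, each with 0 siLox arrays above background, and of the scr arrays Alox5 was above background on 3 and Rgs7bp on 2.

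In all, 9746 of 22644 genes differed between siLox and scr (4382 higher and 5364 lower in siLox), of which 823 changed by at least 1 on the log2 scale (479 higher and 344 lower). The groups did not overlap for 6926 genes (30.6%, where chance gives 2.86%). Fitted on the 8 arrays of slide 1 alone, whose median spread within groups (SD 0.163) exceeded that of slide 2 (SD 0.0969), 5653 genes passed (2595 higher and 3058 lower), of which 5586 were among the 9746. In that fit 8 of 19 elastic fibre genes, 8 of 17 collagens and 7 of 24 cholesterol genes remained lower, and 2 of 17 leukocyte markers higher. Of 27 NF-kB targets 11 were higher, 10 of them among the 16 and Saa3, named after its value was seen, only there (0.86, adjusted p = 0.0293), while Eln, Aspn, Lum, Plod2, P4ha1, Tgfbi, Cxcl2, Csf3, Csf2, Egr1, Itgax, Laptm5, Tyrobp, Cd83 and Shisal1 no longer passed. With replicate 4 of both groups left out, a check chosen after the data were seen, 11349 genes passed.

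The comparison of siLoxl1 with siLoxl2 tests the difference between these knockdowns directly, within slide 2. Interferon response genes were lower in siLoxl1. Of 42 such genes, 39 were lower and 0 higher (40 adjusted over the list alone), with a median of −1.16. The antiviral genes Mx1 (−2.78 ± 0.42), Ifit3 (−2.02 ± 0.19), Mx2 (−2.01 ± 0.26) and Oasl2 (−1.91 ± 0.17) were among them. The list was called lower (adjusted p = 7.31e-80) and kept the call with an estimated correlation (adjusted p = 0.0124), but not when the correlation was estimated from the 8 arrays of slide 2 alone (adjusted p = 0.409). The mean of the list over all its genes, relative to all arrays, was −2.04 ± 0.26 (SD, n = 4) in siLoxl1 and −0.87 ± 0.18 (SD, n = 4) in siLoxl2. Of 27 inflammatory cytokines and NF-kB targets, 0 passed the threshold of the limma test (0 adjusted over the list alone, 1 at an unadjusted p under 0.05), with Cxcl1 at −0.48 ± 0.44 and Ccl8 at −0.45 ± 0.33. In the 8 arrays of slide 2 alone 1 was higher (Il1rl1, 0.28) and 1 lower (Icam1, −0.17), both named after their values were seen.

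Cell cycle genes were higher in siLoxl1, 11 of 41 with 0 lower (15 adjusted over the list alone). Cenpe was higher by 0.35 ± 0.06, Kif20a by 0.32 ± 0.07, Rrm2 by 0.31 ± 0.06 and Ect2 by 0.30 ± 0.07. The list was called higher (adjusted p = 5.32e-09; adjusted p = 0.255 with an estimated correlation). Genes of the unfolded protein and amino acid response were called lower with 2 of 29 past the threshold (3 adjusted over the list alone), Pdia4 at −0.73 ± 0.12 and Creld2 at −0.28 ± 0.06 (adjusted p = 0.00222; adjusted p = 0.439 with an estimated correlation). The RNA interference machinery was called higher with 1 of 13 past the threshold (8 adjusted over the list alone), Tarbp2 at 0.20 ± 0.04 (adjusted p = 0.0325; adjusted p = 0.255 with an estimated correlation). With the 8 arrays of slide 2 alone that call was lost (adjusted p = 0.0861), while the cell cycle list (adjusted p = 2.42e-06, 13 genes higher) and the unfolded protein list (adjusted p = 4.07e-05, 8 genes lower) kept theirs, and with a correlation estimated from those arrays 0 lists were called (adjusted p = 0.409 for each of the 3). In each of the collagen, collagen processing, elastic fibre and matrix protease lists, 0 genes passed the threshold of the limma test (0 adjusted over the list alone), with 0, 1, 1 and 2 at an unadjusted p under 0.05. In the 8 arrays of slide 2 alone, 2, 2, 1 and 1 passed. Lower in siLoxl1 there were Col6a1 (−0.29, adjusted p = 0.0108), Col6a2 (−0.21, adjusted p = 0.0260, with a second probe at 0.04), Emilin1 (−0.33, adjusted p = 0.0181), Plat (−0.52, adjusted p = 0.0202) and Plod1 (−0.23, adjusted p = 0.0238), and Plod2 was higher (0.28, adjusted p = 0.0254). Plod1 and Plod2 are named here after their values were seen. Among other matrix genes Has2, a hyaluronan synthase (0.43 ± 0.07), and Vcan (0.33 ± 0.07) were higher in siLoxl1 (2 adjusted over the list alone). The median of that list was 0.02 and its mean −0.13, owing to Fn1, which read −2.60 on siLoxl1 replicate 4 alone.

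The other lists held few differences between siLoxl1 and siLoxl2, and none of them was called in the fit of 16 arrays or with the 8 arrays of slide 2 alone. The 8 arrays gave up to 6 changed genes in each of them. TGF-beta and BMP signalling gave 2 higher of 30 (6 adjusted over the list alone), the receptor gene Bmpr2 (0.42 ± 0.08) and Id2 (0.20 ± 0.05). Hypoxia and glycolysis gave 2 higher of 26 (2 adjusted over the list alone), Hk2 (0.25 ± 0.05) and Kdm3a (0.16 ± 0.04). Cholesterol synthesis gave Sc5d (0.27 ± 0.05), immediate early genes Klf2 (0.20 ± 0.04) and heat shock genes Hspd1 (0.15 ± 0.04), each 1 higher with 1 adjusted over the list alone, and Hspd1 did not pass in the 8 arrays of slide 2 alone. The endothelial markers Tek (−0.86 ± 0.20, above background on 3 of 4 siLoxl1 arrays) and Vwf (−0.50 ± 0.10) and the myeloid marker Ly6g (−0.84 ± 0.16) were lower in siLoxl1, and the mesothelial marker Wt1 was higher (0.26 ± 0.06).

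Besides Mx1, the single genes with the furthest differences were Clec4e, a C-type lectin receptor gene (−3.44 ± 0.31), and Ifit3b (−2.14 ± 0.18), lower in siLoxl1. Gbp4 was at least 2.16-fold lower, with 0 siLoxl1 arrays above background. Tnfsf10 was above background on 1 siLoxl2 array and on 0 siLoxl1 arrays, so no fold is given. Lce3a (1.60 ± 0.22), the chemokine gene Pf4 (1.20 ± 0.15), Erich2 (0.92 ± 0.15), Bst1 (0.80 ± 0.12) and Pla2g7 (0.76 ± 0.12) were higher, with Erich2 above background on 1 of 4 siLoxl2 arrays. A second Pla2g7 probe read only 0.15. The family members Lox (−0.14 ± 0.24), Loxl3 (0.09 ± 0.07) and Loxl4 (−0.34 ± 0.09, adjusted p = 0.0508) did not pass the threshold. With the 8 arrays of slide 2 alone Loxl4 passed (adjusted p = 0.0205), and both Loxl4 probes, the second at −0.18, gave an exact two-sided permutation p of 0.0286. In all, 905 genes differed (585 higher and 320 lower in siLoxl1), 102 of them by at least 1 on the log2 scale (5 higher and 97 lower), and the groups did not overlap for 4597 genes (20.3%, where chance gives 2.86%). The 8 arrays of slide 2 alone gave 1993 genes (1382 higher and 611 lower), among them 845 of the 905. With 1 array left out the count was between 444 (without siLoxl2 replicate 4) and 626 (without siLoxl1 replicate 4). The share higher, 64.6%, was 42.8% of 579 genes with quantile normalization, 43.3% of 580 in the value table of the authors and 50.6% of 508 with no filter on dim probes, and 69.2% of 1330 with normexp, 70.5% of 1159 with trend and robust eBayes and 73.0% of 3612 with array weights.

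**Figure D3:**
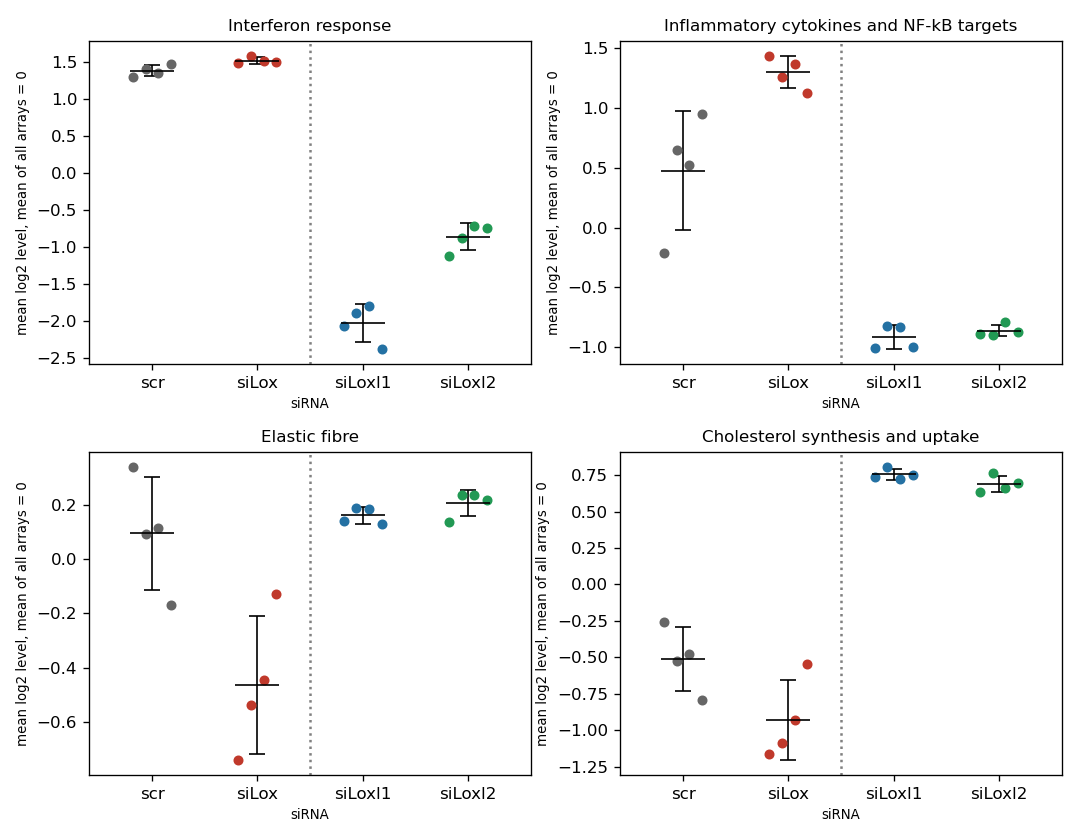
Mean log2 level of 4 gene lists in each of the 16 arrays, relative to the mean of all arrays; points are arrays, bars are group means with the standard deviation of 4 arrays, and the dotted line parts slide 1 from slide 2. Interferon response genes average 1.38 in scr, 1.52 in siLox, −2.04 in siLoxl1 and −0.87 in siLoxl2.

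The comparison of siLoxl1 with scr asks which transcripts change when Loxl1 is knocked down, but it sets slide 2 against slide 1. Interferon response genes were lower in siLoxl1, 41 of 42 with 0 higher (41 adjusted over the list alone), with a median of −3.29. Mx1 stood at −6.61 ± 0.42, Mx2 at −6.19 ± 0.26, Oas3 at −5.38 ± 0.14 and Oas2 at −5.36 ± 0.17 (list adjusted p = 1.51e-34; adjusted p = 0.236 with an estimated correlation). The interferon gene Ifnb1 itself stood at −8.36 ± 0.45, above background on 1 of 4 siLoxl1 arrays. Among inflammatory cytokines and NF-kB targets, 15 of 27 were lower and 4 higher (19 adjusted over the list alone), with Csf2 at −6.92 ± 0.55, Cxcl1 at −6.22 ± 0.44 and Tnfaip3 at −4.09 ± 0.31, and Cxcl2 at least 37.9-fold lower (adjusted p = 0.000198; adjusted p = 0.601 with an estimated correlation). Cholesterol genes were higher, 23 of 24 with 0 lower (23 adjusted over the list alone), with Insig1 at 2.30 ± 0.25 and Msmo1 at 1.83 ± 0.15 (adjusted p = 1.97e-06; adjusted p = 0.668 with an estimated correlation). Hypoxia and glycolysis genes were higher too, 23 of 26 with 0 lower (24 adjusted over the list alone), with Ankrd37 at 2.01 ± 0.07 and Car9 at 1.98 ± 0.09 (adjusted p = 1.57e-05; adjusted p = 0.593 with an estimated correlation). Cell cycle genes were lower, 31 of 41 with 4 higher (35 adjusted over the list alone), with Plk1 at −1.34 ± 0.06 (adjusted p = 2.28e-09; adjusted p = 0.309 with an estimated correlation).

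Matrix genes moved apart in siLoxl1 against scr. Of 17 collagens, 9 were lower and 2 higher (11 adjusted over the list alone), with Col14a1 at −3.43 ± 0.28, Col6a3 at −2.17 ± 0.15 and Col5a3 at −2.17 ± 0.09 (adjusted p = 0.00169; adjusted p = 0.668 with an estimated correlation). Of 19 elastic fibre genes, 9 were higher and 6 lower (15 adjusted over the list alone), with Eln at −4.66 ± 0.33 but Emilin2 at 2.56 ± 0.08 and Efemp1 at 2.40 ± 0.11, and the list was not called (adjusted p = 0.979). The matrix protease gene Mmp3 was higher by 5.26 ± 0.17 and Mmp8 by 3.72 ± 0.15. Mesothelial markers were lower, 7 of 9 with 2 higher (9 adjusted over the list alone), with Wt1 at −2.38 ± 0.06 and Bnc1 at −2.15 ± 0.10 (adjusted p = 0.00169; adjusted p = 0.309 with an estimated correlation). The epithelial keratin gene Krt8 stood at −4.24 ± 0.15, the endothelial marker Esam at −3.40 ± 0.14 and the pericyte marker Rgs5 at −4.13 ± 0.64 (above background on 2 of 4 siLoxl1 arrays). The lists of pericyte markers (adjusted p = 0.0209; adjusted p = 0.668 with an estimated correlation) and of the lysyl oxidase family (adjusted p = 0.0426; adjusted p = 0.512 with an estimated correlation) were called lower as well. In the family Loxl4 stood at −0.85 ± 0.09 and Loxl3 at −0.17 ± 0.07.

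Besides Mmp3, the furthest changes in siLoxl1 against scr were those of Akr1c18 (6.23 ± 0.13), S100a8 (6.01 ± 0.16), Serpina3n (5.20 ± 0.38) and Fmo2 (4.88 ± 0.47), higher in siLoxl1 (Serpina3n above background on 1 of 4 scr arrays and Fmo2 on 3), with Gdf10 at least 10.98-fold, Lce3a at least 10.5-fold and Bdkrb2 at least 7.93-fold higher. Besides Ifnb1, Csf2, Mx1 and Cxcl1, the interferon-inducible Phf11b was lower (−6.22 ± 0.23), Cxcl9 was at least 81.3-fold lower and Gbp4 at least 49.2-fold lower. The Cxcl9 bound holds for its brightest probe only, and a second Cxcl9 probe read −5.34 (log2), a smaller change. In all, 14744 genes differed (9793 higher and 4951 lower), 3289 of them by at least 1 on the log2 scale (2066 higher and 1223 lower), and 13189 did not overlap between the groups (58.2%, where chance gives 2.86%). The median of all genes was 0.19 and moved to −0.07 with another background correction (normexp). The share higher, 66.4%, was 45.7% with normexp, 55.5% with quantile normalization, 55.4% in the value table of the authors and 44.4% with no filter on dim probes, so that a direction for the genes as a whole depends on the scaling.

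The comparison of siLoxl2 with scr asks the same for Loxl2 and also sets slide 2 against slide 1. Its pattern resembled that of siLoxl1. Interferon response genes were lower, 41 of 42 with 0 higher (41 adjusted over the list alone), with a median of −2.19, Ccl5 at −4.70 ± 0.21, Mx2 at −4.18 ± 0.26 and Mx1 at −3.84 ± 0.42 (adjusted p = 5.74e-27; adjusted p = 0.231 with an estimated correlation). Of 27 inflammatory cytokines and NF-kB targets, 15 were lower and 5 higher (20 adjusted over the list alone), with Csf2 at −6.89 ± 0.55 (above background on 3 of 4 siLoxl2 arrays) and Cxcl1 at −5.74 ± 0.44 (adjusted p = 0.000865; adjusted p = 0.639 with an estimated correlation). All 24 cholesterol genes were higher (24 adjusted over the list alone), with Insig1 at 2.18 ± 0.25 (adjusted p = 9.16e-07; adjusted p = 0.639 with an estimated correlation). Of 26 hypoxia and glycolysis genes, 24 were higher (24 adjusted over the list alone), with Car9 at 2.00 ± 0.09 (adjusted p = 4.37e-06; adjusted p = 0.637 with an estimated correlation). Of 41 cell cycle genes, 35 were lower and 3 higher (38 adjusted over the list alone), with Plk1 at −1.60 ± 0.06 (adjusted p = 4.13e-13; adjusted p = 0.231 with an estimated correlation). Of 17 collagens, 8 were lower and 2 higher (10 adjusted over the list alone), with Col14a1 at −3.42 ± 0.28 (adjusted p = 0.00602; adjusted p = 0.745 with an estimated correlation). Of 9 mesothelial markers, 7 were lower and 2 higher (9 adjusted over the list alone), with Wt1 at −2.64 ± 0.06 (adjusted p = 0.00368; adjusted p = 0.396 with an estimated correlation).

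The furthest changes in siLoxl2 against scr were those of Akr1c18 (5.98 ± 0.13), Serpina3n (5.43 ± 0.38), S100a8 (5.33 ± 0.16), Mmp3 (5.20 ± 0.17) and Gda (4.72 ± 0.21), higher in siLoxl2 (Serpina3n above background on 1 of 4 scr arrays), with Derl3 at least 27.3-fold, Snhg11 at least 10.2-fold and Gdf10 at least 9.85-fold higher. Besides Csf2 and Cxcl1, Ifnb1 (−7.04 ± 0.45) and Traf1 (−5.88 ± 0.42) were lower, Cxcl9 was at least 74.9-fold, Cxcl2 at least 34.9-fold, Cxcl3 at least 15.2-fold and Ifna4 at least 12.3-fold lower. The bounds of Cxcl9 and Snhg11 hold for their brightest probes only. A second Cxcl9 probe read −5.56 and a second Snhg11 probe 2.99 (log2), both smaller changes. Loxl4 (−0.52 ± 0.09) and Loxl3 (−0.26 ± 0.07) were lower, and Loxl1 did not pass the threshold (0.18 ± 0.10). A second Loxl1 probe read 0.25 (limma adjusted p = 0.0490 over all probes; exact two-sided permutation p = 0.143). In all, 14667 genes differed (9372 higher and 5295 lower), 3117 of them by at least 1 on the log2 scale (1931 higher and 1186 lower), and 12977 did not overlap between the groups (57.3%, where chance gives 2.86%). The median of all genes was 0.17 and −0.09 with normexp. The share higher, 63.9%, was 44.1% with normexp, 53.8% with quantile normalization, 53.7% in the value table of the authors and 43.1% with no filter on dim probes.

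The comparisons of siLox with siLoxl1 and with siLoxl2 test the differences between these knockdowns, again across the slides. All 42 interferon response genes were higher in siLox than in siLoxl1 (42 adjusted over the list alone), with a median of 3.46, and than in siLoxl2 (42 adjusted over the list alone), with a median of 2.24. Against siLoxl1 this list had an adjusted p of 7.39e-31 (adjusted p = 0.324 with an estimated correlation), and against siLoxl2 one of 2.37e-24 (adjusted p = 0.419 with an estimated correlation). Mx1 stood at 7.87 ± 0.42 against siLoxl1 and at 5.10 ± 0.42 against siLoxl2. All 24 cholesterol genes were lower in siLox in both comparisons (24 adjusted over the list alone in each), with Insig1 at −2.84 ± 0.25 and −2.71 ± 0.25. Those calls had adjusted p = 9.73e-07 and 4.06e-07 and were lost (adjusted p = 0.646 and 0.608 with an estimated correlation). Lox was lower in siLox (−3.61 ± 0.24 and −3.75 ± 0.24). Loxl1 was higher in siLox than in siLoxl1 (0.49 ± 0.10) and lower than in siLoxl2 (−0.66 ± 0.10), Loxl2 differed by 0.05 ± 0.14 from siLoxl1, which did not pass, and by 0.35 ± 0.14 from siLoxl2, which did. The other 2 Loxl2 probes read 0.73 and 0.63 against siLoxl1, and both passed (limma adjusted p = 9.20e-05 and 0.000291 over all probes). They read 1.11 and 0.97 against siLoxl2. Loxl4 was higher in siLox (0.98 ± 0.09 and 0.64 ± 0.09), and Loxl3 was higher than in siLoxl2 (0.22 ± 0.07) but did not pass against siLoxl1 (0.14 ± 0.07).

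Inflammatory cytokines and NF-kB targets were higher in siLox than in siLoxl1, 20 of 27 with 3 lower (23 adjusted over the list alone), and than in siLoxl2, 18 of 27 with 3 lower (23 adjusted over the list alone), with Tnfaip3 at 5.27 ± 0.31 and 5.39 ± 0.31. Those calls had adjusted p = 2.70e-06 and 9.17e-06 (adjusted p = 0.565 and 0.535 with an estimated correlation). Cell cycle genes were higher in siLox, 24 of 41 with 4 lower against siLoxl1 (28 adjusted over the list alone) and 30 with 3 lower against siLoxl2 (33 adjusted over the list alone), with Plk1 at 1.02 ± 0.06 and 1.28 ± 0.06 (adjusted p = 2.38e-05 and 3.11e-08; 0.565 and 0.419 with an estimated correlation). Hypoxia and glycolysis genes were lower in siLox, 24 and 25 of 26 (24 and 25 adjusted over the list alone), with Ankrd37 at −2.15 ± 0.07 and −1.94 ± 0.07 (adjusted p = 1.85e-05 and 6.64e-06; 0.605 and 0.535 with an estimated correlation). Matrix proteases were lower in siLox, 15 and 16 of 22 (18 and 17 adjusted over the list alone), with Mmp3 at −4.78 ± 0.17 and −4.72 ± 0.17 (adjusted p = 0.0499 and 0.0277; 0.844 and 0.880 with an estimated correlation). Mesothelial markers were higher in siLox, 7 of 9 with 2 lower in both comparisons (9 adjusted over the list alone in each), with Wt1 at 2.04 ± 0.06 and 2.30 ± 0.06 (adjusted p = 0.0159 and 0.0277; 0.565 and 0.535 with an estimated correlation). Against siLoxl1 alone, immediate early genes were called higher, 12 of 22 with 7 lower (19 adjusted over the list alone), with Egr1 at 3.19 ± 0.28 (adjusted p = 0.0499; 0.646 with an estimated correlation). Ribosomal protein genes were called lower there, 20 of 24 with 1 higher (21 adjusted over the list alone), with Rpl4 at −0.95 ± 0.05 (adjusted p = 0.0499; 0.844 with an estimated correlation), and quantile normalization turned the median from −0.27 to 0.03.

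The genes with the furthest differences between siLox and siLoxl1 were Ifnb1 (9.50 ± 0.45), Csf2 (8.71 ± 0.55) and Cxcl1 (8.16 ± 0.44), higher in siLox, with Cxcl9 at least 186-fold and Cxcl2 at least 169-fold higher, and Fmo2 (−5.85 ± 0.47) and Akr1c18 (−5.78 ± 0.13), lower in siLox, with Serpina3n at least 32.6-fold, Aqp8 at least 16.4-fold and Lce3a at least 10.2-fold lower. Ifnb1 was above background on 1 of 4 siLoxl1 arrays and Fmo2 on 2 of 4 siLox arrays, so that their ranks are uncertain. Between siLox and siLoxl2 they were Csf2 (8.68 ± 0.55), Ifnb1 (8.17 ± 0.45) and Cxcl1 (7.68 ± 0.44), with Cxcl9 at least 171-fold and Cxcl2 at least 155-fold higher, and Akr1c18 (−5.53 ± 0.13), Fmo2 (−5.33 ± 0.47) and Gda (−5.29 ± 0.21), with Serpina3n at least 38.4-fold and Derl3 at least 27.7-fold lower. Csf2 was above background on 3 of 4 siLoxl2 arrays. Both Cxcl9 bounds hold for its brightest probe only. A second Cxcl9 probe read 6.59 against siLoxl1 and 6.81 against siLoxl2 (log2), smaller differences. In each of these comparisons 16406 genes differed, 5579 higher and 10827 lower in siLox than in siLoxl1, and 5847 higher and 10559 lower than in siLoxl2. By at least 1 on the log2 scale, 4672 differed from siLoxl1 (1751 higher and 2921 lower) and 4579 from siLoxl2 (1801 higher and 2778 lower). The groups did not overlap for 15572 genes (68.8%) and 15546 genes (68.7%), where chance gives 2.86%. The median of all genes was −0.25 and −0.22, and 0.07 and 0.09 with normexp. The share higher, 34.0% and 35.6%, was 53.6% and 54.9% with normexp and 54.8% and 55.4% with no filter on dim probes.

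The fold changes of the 3 siRNAs against scr were set side by side across 22644 genes, which are not independent replicates. The siLoxl1 and siLoxl2 fold changes had a Pearson r of 0.962, and 0.884 when each was set against a different pair of scr arrays. Groups with no effect that share 4 control arrays gave r = 0.502 and a covariance of 0.018 in 100 simulations, against a measured covariance of 0.623. The simulation gave all groups the same spread per gene, while slide 1 with scr varied more (median SD 0.163) than slide 2 (0.0969). A larger spread in scr raises the r and the covariance expected with no effect. Both simulated values are therefore too low as references, and no simulation with the spread of each slide was run. Of the genes higher against scr, 8629 were shared by siLoxl1 and siLoxl2 (4053 if the lists were independent), and of those lower 4457 (1158 if independent). Both groups share slide 2 as well. The siLox fold changes had r = −0.080 with those of siLoxl1 and r = −0.087 with those of siLoxl2 (jackknife SE 0.0571 and 0.0600 over the arrays), each within 2 SE of 0. For groups with no effect that share controls the simulated value is 0.502 and not 0, so nearness to 0 does not show that the fold changes are unrelated. With the scr arrays split, r ranged from −0.266 to 0.0149 and from −0.283 to 0.0182 over 6 splits. Their covariances were −0.0293 and −0.0296, below the simulated 0.018 by 0.0473 and 0.0476, and no error was estimated for that difference. Of the genes higher against scr, 1642 were shared by siLox and siLoxl1 (1895 if independent), and 1493 by siLox and siLoxl2 (1814 if independent).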

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

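Tests chosen only after the result was seen are those of leukocytes, of the shared batch and of the fibroblast share. In groups of 4 arrays, an array was singled out when its gap to the nearest other array relative to the range of the group exceeded Dixon's critical value. Chance alone passes about 1 in 20 groups, and 24 of 482 groups passed (4.98%), 23 of 370 for single genes, 1 of 100 for list means and 0 of 12 for array measures. Levels below are log2 signals relative to the 75th percentile.

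The Fn1 probe read −2.60 on siLoxl1 replicate 4 and 8.25 to 8.33 on the other siLoxl1 arrays. On siLox replicate 4, Ankrd37 stood at 0.72 (0.41 to 0.42 on the others), Fmod at −1.24 (−2.05 to −1.92), Loxl3 at 2.79 (2.52 to 2.57), Mx2 at 5.95 (6.24 to 6.29) and Plod2 at 2.46 (2.07 to 2.10). On siLoxl1 replicate 3, Cxcl9 stood at −6.94 (−8.31 to −8.13), Efemp1 at 5.20 (5.34 to 5.35), Eln at −3.81 (−4.40 to −4.30), Gdf10 at −0.85 (−1.40 to −1.36), Ifnb1 at −3.98 (−6.36 to −6.02) and Il1rl1 at 5.028 (5.145 to 5.161). Cxcl2 stood at −6.46 on siLoxl1 replicate 2 (−8.36 to −8.18), Cxcl3 at −7.32 on siLoxl2 replicate 3 (−7.83 to −7.75) and Cxcl9 at −8.03 on siLoxl2 replicate 2 (−6.20 to −6.01). Bmpr2 stood at 0.61 on siLoxl2 replicate 4 (0.86 to 0.89), where the mean of the pericyte list was −0.0039 (−0.28 to −0.24), and Loxl1 at 5.65 on siLoxl2 replicate 1 (5.78 to 5.80). Adamtsl4 stood at −1.01 on siLox replicate 2 (−1.23 to −1.19). In scr, Gdf10 stood at −6.41 on replicate 2 (−6.69 to −6.68), Ifna4 at −1.86 on replicate 4 (−2.50 to −2.42), Mmp3 at 0.11 on replicate 1 (−0.11 to −0.08), Plk1 at 5.27 on replicate 3 (5.37 to 5.38) and Saa3 at 0.96 on replicate 1 (1.51 to 1.54).

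Interferon response genes were lower in siLoxl1 than in siLoxl2, on 1 slide. Place on the slide, labelling or scaling would move the spike-in probes too, and their median differed by 0.0552 (−0.9861 to 0.1244 over 10 probes, 3 of them lower in siLoxl1). More leukocytes in the siLoxl2 cultures that moved both lists alike would lower the leukocyte list in siLoxl1 as far as the interferon list. Its median lay above that of the interferon list by 1.063 (SE 0.1857 over genes). The test does not cover a change in leukocytes too small to move the marker list as far. With the technical explanations tested here argued against, a lower interferon response under siLoxl1 than under siLoxl2 remains a hypothesis that may be biological, and whether it comes from the targeted genes or from the siRNA molecules themselves was not tested.

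Interferon response genes were also lower in siLoxl1 and siLoxl2 than in scr. The slides had separate scans, with 1 scan pass on slide 1 and 2 on slide 2. A scanner, labelling or scaling difference that lowered all signals of slide 2 alike would lower its spike-in probes. Their median was higher there by 0.5808, which argues against such a uniform drop only. Of 10 probes, 8 were higher and the 2 with the lowest signals were lower, the furthest at −1.0099. The median of the interferon list was −3.29 in siLoxl1 and −2.19 in siLoxl2. The spike-in difference varied with the signal, so this test does not exclude a slide difference that depends on the signal. A culture or transfection batch shared by the arrays of a slide cannot be told apart from the siRNAs, since each group lies on 1 slide only. The interferon list moved by 0.1462 between siLox and scr on slide 1, which leaves that batch open, as does the siRNA.

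Matrix genes were lower and NF-kB genes higher in siLox than in scr. Place on the slide, labelling or scaling would move the spike-in probes, whose median differed by −0.0876. A lower share of fibroblasts with all other cell types raised alike would move the mesothelial and leukocyte lists together. The mesothelial list lay below the leukocyte list by a difference of −0.7929 (SE 0.1827 over genes), which argues against that case. A lower share of fibroblasts with more leukocytes alone would give such a difference too, so the test cannot speak against it. The mesothelial mean did not rise (0.46 in scr and 0.23 in siLox), while the leukocyte means of the groups overlapped. More leukocytes in the siLox cultures may still account for part of it: the leukocyte median minus the NF-kB median was −0.4253 (SE 0.2684), within 2 SE. The leukocyte markers with the brightest probes were Itgam (3.80 in scr and 3.76 in siLox), Lyz1 (2.57 and 3.08) and Csf1r (2.24 and 2.35), and signals of different probes do not rank transcripts by abundance. The shift of the leukocyte list itself was matched by 4 of 35 splits of these arrays, so that chance is not excluded for it. The knockdown of Lox stays open beside it.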

How the results depend on the processing

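Tests chosen only after the result was seen are those that leave out replicate 4 of both scr and siLox and the list calls from 8 arrays. Over 18 results that answer a comparison, 280 of 317 alternative values stayed on the same side or within 1.5 times, and 37 moved. Of 2475 values for single lists, 2258 stayed, 105 lost a call, 108 gained one and 4 reversed. Of 4455 values for named genes, 4243 stayed, 179 lost a call, 33 gained one and 0 reversed.

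With a log2 fold change of at least 1 asked for, fewer genes can pass: 823 (siLox vs scr), 3289 (siLoxl1 vs scr), 3117 (siLoxl2 vs scr), 4672 (siLox vs siLoxl1), 4579 (siLox vs siLoxl2) and 102 (siLoxl1 vs siLoxl2). The 8 arrays of the groups compared gave 5653 for siLox vs scr and 1993 for siLoxl1 vs siLoxl2, in line with the different spread of the slides. For siLoxl1 vs siLoxl2, quantile normalization gave 579, the value table of the authors 580, no filter 508 and array weights 3612, and the cause was not tested. With an estimated correlation camera called 0, 0, 0, 0, 0 and 1 lists in the same order of comparisons. With normexp it called 19 lists (siLox vs scr), 15 (siLox vs siLoxl1) and 13 (siLox vs siLoxl2), and with no filter 21, 14 and 13, and the cause was not tested. The correlation of fold changes was −0.145 (siLox and siLoxl1), −0.160 (siLox and siLoxl2) and 0.972 (siLoxl1 and siLoxl2) with normexp, 0.941 for the last with no filter and 0.884 with split controls, which removes the shared arrays. The ribosomal list reversed to 0.0287 (quantile) and 0.0281 (value table) in siLox vs scr, and to 0.0283 and 0.0282 in siLox vs siLoxl1, and the cause was not tested.

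With 1 array left out, counts of genes were 8017 to 10954 (siLox vs scr), 13934 to 15055 (siLoxl1 vs scr), 13779 to 14963 (siLoxl2 vs scr), 15726 to 16327 (siLox vs siLoxl1), 15696 to 16351 (siLox vs siLoxl2) and 444 to 626 (siLoxl1 vs siLoxl2). The last was 905 with all arrays and 526, 465, 497 and 626 without siLoxl1 replicates 1 to 4 and 603, 532, 562 and 444 without siLoxl2 replicates 1 to 4. Lists called were 10 to 17, 8 to 9, 7 to 8, 6 to 9, 7 to 8 and 3 to 6 in that order, with 17 without siLox replicate 4 against 11. Lox ranged from −3.22 to −2.67, Loxl1 from −1.05 to −0.91 and Loxl2 from −1.18 to −0.95, and the correlations from −0.0971 to −0.0241, −0.105 to −0.0294 and 0.958 to 0.965. Without replicate 4 of both scr and siLox, 11349 genes passed and 15 lists were called. A slide block changed no estimate within a slide, and for comparisons between slides it could not be fitted, nor could a random slide block, since each group lies on 1 slide. Signal over background limits which probes were tested. Without the filter 34731 genes were tested, and more passed in the 4 comparisons between slides (22069, 21755, 23988 and 23772) and fewer in both within a slide (8333 for siLox vs scr and 508 for siLoxl1 vs siLoxl2).

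The replicate numbers were not taken to pair the samples, since for no comparison did every pair of equal numbers correlate above 0.1 in the differences from the group means: r was −0.119, −0.0205, −0.0021 and −0.186 for siLox and scr, and 0.12, 0.22, 0.13 and 0.043 for siLoxl1 and siLoxl2. In the latter, each array correlated best with its own number, a hint from the data and not from the design, and the number is also the slide column. With the replicate block, 9210 (siLox vs scr), 14550 (siLoxl1 vs scr), 14437 (siLoxl2 vs scr), 16308 (siLox vs siLoxl1), 16282 (siLox vs siLoxl2) and 605 genes (siLoxl1 vs siLoxl2, 339 higher and 266 lower) passed. The share higher in the last was 56.0% against 64.6% without the block, and 574 of the 605 were among the 905.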

Other observations

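The tests on numbers of genes and lists and on the 5 single lists named first were planned, and those on the other called lists were chosen after their results were seen. Each comparison was set against all 35 splits of its 8 arrays into 4 and 4, the real one included. For numbers of genes, only the real split was as large in each comparison (1 of 35, the smallest share that this test allows). Within a slide it gave 9746 genes in siLox vs scr (highest other 7233) and 905 in siLoxl1 vs siLoxl2 (0). Between slides it gave 14744 in siLoxl1 vs scr (0) and 14667 in siLoxl2 vs scr (15). It gave 16406 both in siLox vs siLoxl1 (0) and in siLox vs siLoxl2 (1). In the comparisons between slides, the real split is also that of the slides. Any slide difference would give this outcome there, so the test cannot speak for the siRNAs. The split with 7233 genes exchanged replicate 4 of scr with replicate 4 of siLox, which points to a structure of the slide 1 samples that runs across the groups.

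For numbers of lists called by camera with its preset correlation, chance cannot be excluded. As many lists as in the real split were called in 11 of 35 splits for siLox vs scr (11 lists, highest other 15), 12 for siLoxl1 vs scr (9, highest other 13), 18 for siLoxl2 vs scr (7, highest other 13), 7 for siLox vs siLoxl1 (9, highest other 14), 13 for siLox vs siLoxl2 (7, highest other 13) and 9 for siLoxl1 vs siLoxl2 (4, highest other 5). Why lists were called in splits that mix the groups was not tested.

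For single lists, the median of the interferon list between siLoxl1 and siLoxl2 was 1.16 in size (highest other split 0.8177, 1 of 35 as large), and that of the NF-kB list between siLox and scr was 0.878 (highest other 0.6507, 1 of 35). In both of these planned tests only the real split was as large, the smallest share that the test allows. Chance cannot be excluded for siLox vs scr in the elastic fibre list (0.4655, highest other 0.5364), the collagens (0.5248, highest other 0.5906) or the cholesterol list (0.4833, highest other 0.5248), with 2 of 35 splits as large in each. Nor can it for 6 of the other lists called in siLox vs scr: the leukocyte markers (0.4528, highest other 0.4921, 4 of 35), myofibroblast genes (0.1976, highest other 0.2226, 3 of 35), ribosomal proteins (0.0933, highest other 0.1014, 3 of 35), collagen processing (0.3311, highest other 0.3547), other matrix genes (0.3868, highest other 0.4126) and pericyte markers (0.453, highest other 0.5259), the last 3 with 2 of 35. Nor can it for the unfolded protein list in siLoxl1 vs siLoxl2 (0.0668, highest other 0.0865, 4 of 35). Only the real split was as large (1 of 35) for TGF-beta and BMP signalling in siLox vs scr (0.2237, highest other 0.2146) and, in siLoxl1 vs siLoxl2, for the cell cycle (0.1494, highest other 0.1443) and the RNA interference machinery (0.1493, highest other 0.0887). These lists were tested because camera had called them in the same data. The shares of single lists are not adjusted for the 15 lists tested, so 1 of 35 does not by itself exclude chance for a list among them.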
